A study of Mus musculus with 6 samples.

How the data were processed

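Chromatin from mouse embryonic stem cells was crosslinked with 1% formaldehyde for 10 min and sheared to 200 to 500 bp, and 8 μg of Tet1 antibody or IgG was used for each immunoprecipitation, per the labels' protocols. The labels state that the chromatin came from a pair of biologically independent samples. Each deposited file lists aligned reads, 1 per line, with chromosome, start, end and strand. The files hold no counts per region and no scaled values; repeated positions were kept as deposited. Reads came from an Illumina Genome Analyzer, per the labels, and were placed on mm8, per the submitters' processing notes; the aligner and its rules for mismatches and multiple hits were not given in the sources used here. Reads were 25 bp long in Tet1 control 1, Tet1 KD 3, Tet1 KD 4 and IgG control 1 and 36 bp in Tet1 control 2 and IgG control 2. In the deep set 56.8% to 57.4% of reads lay on the plus strand and the mitochondrial genome and unplaced contigs were listed, while the shallow set was even between strands and listed chromosomes 1 to 19, X and Y only. The sets therefore differ in more than depth. Each group has 1 library of each set.

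Chromosomes 1 to 19, X and Y were used for all comparisons. Reads sharing a position and strand were counted once per library, each read was moved 150 bp toward its 3' side, and reads were summed over 1 kb bins. Bins with at least 30 reads over the 6 libraries were tested (1543116 of 2630738 bins). Libraries were scaled by all reads counted, as planned, so a change uniform over the genome would not be seen. TMM factors (trimming 30% of log ratios and 5% of mean levels at each end, from 10 kb bins) were an alternative; they were 0.881 and 0.888 in Tet1 control, 1.05 and 1.08 in Tet1 KD and 1.05 and 1.07 in IgG control, and moved the median log2 difference of all bins by 0.234 for Tet1 control over IgG and by -0.233 for Tet1 KD over Tet1 control.

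The gene annotation at hand belongs to another assembly than the reads, and coordinates were not converted. Promoters, gene lists, CpG classes and profiles around transcription start sites, all planned before the data were examined, were therefore left out, and the residual signal, the agreement of the control libraries and the profiles were computed on bins and on runs of touching enriched bins instead.

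The main test across bins is not the test planned. A negative binomial quasi-likelihood test had been planned, but edgeR was not used because the files hold no deposited counts. limma voom was fitted to the bins first and its numbers of called bins were seen. It then recovered almost nothing in a first simulation, as did a first version of a quasi-Poisson test. Both the estimate of the spread in that test and the simulation were then changed. In the final simulation both tests recovered changed bins about equally: of 50 bins raised 4-fold in Tet1 control, the quasi-Poisson test called 92% and voom 94% over IgG, and of 50 bins raised 2-fold each called 8%. A further 40000 bins were raised 4-fold in that simulation, and bins with few IgG and Tet1 KD reads were not raised. Recovery was counted at the simulation's own adjusted threshold. It was not counted at the largest p called in the data, so it does not give the recovery there. The quasi-Poisson test was kept as the main test because it is nearest to the planned one and because it called 249 higher and 229 lower among 1368024 unchanged simulated bins, against 802 and 972 for voom, at each test's own adjusted threshold in the simulation. Unchanged simulated bins were also counted at the largest unadjusted p called in the data, a check added after the data had been seen. The main test was thus chosen after the data had been seen.

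The quasi-Poisson test fitted 1 rate per group and library size to all 6 libraries (3 groups, 3 residual degrees of freedom). The reads of a group were pooled, so its rate and fold rest mostly on its deep library. For Tet1 KD these were 31881256 positions in Tet1 KD 3 and 2276009 in Tet1 KD 4. The Pearson dispersion of each bin was averaged with the mean of bins of similar read number, weighted by 22.8 prior degrees of freedom estimated from the bins, and was not allowed under 1. Contrasts were two-sided likelihood-ratio F tests with Benjamini-Hochberg adjustment at 0.05. Log2 folds used 0.5 reads added per library in proportion to its size. With 2 libraries per group, p-values rest on the spread between these libraries, taken mostly from the mean of bins of similar read number. That spread includes the difference between the depth sets and, in control groups, between wild-type and mock cells.

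For each matched pair, Tet1 and IgG reads per bin were compared by a one-sided exact conditional binomial test (Benjamini-Hochberg 0.01, at least 2-fold). These tests compare 1 library with 1 other and have no replicate error. In simulated data 119 of 1493116 unchanged bins were called in the wild-type pair and 1 in the mock pair. Bins called in one pair were measured in the other set. For the signal left after knockdown, the 95% interval came from 2000 resamplings of 1 Mb blocks. For bins called lower than IgG it came from 2000 resamplings of single bins, which treats neighbouring bins as independent. Shares of reads carry 95% Wilson intervals, and ratios of bins with few reads exact (Clopper-Pearson) intervals; a group with 0 reads was set to 3 reads over the group for a lower bound. Repeated reads have no molecular identifiers, so intervals and bounds cover counting error only.

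Named bins were the 5 with the largest log2 fold past the threshold in each direction, with at least 60 reads over the 6 libraries, on the same side in both matched pairs (Tet1 control over IgG) or with both Tet1 KD libraries on one side of both Tet1 control libraries. This rule, the groups and most alternatives were fixed before the data were examined; the regions, the widest regions named and the depth set as a block were chosen afterwards. Alternatives were 2 kb bins, all reads as deposited, TMM factors, at least 60 reads, a replicate block, leaving out each library, limma voom, the depth set as a block and this block with TMM factors. Positions are given from 1; whether the deposited starts count from 0 or 1 was not given in the sources used here, which could move a bin's content by 1 bp. Work was done in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3 (limma 3.58.1).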

Results

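Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map Tet1 in mouse embryonic stem cells of the E14Tg2A line. Tet1 is a dioxygenase that oxidises methylated cytosine to hydroxymethylcytosine. The 6 libraries formed 3 groups of 2. Tet1 control comprised immunoprecipitations with a rabbit polyclonal Tet1 antibody from wild-type cells (replicate 1) and from cells infected with a lentivirus expressing GFP alone, termed mock (replicate 2). Tet1 KD comprised immunoprecipitations with the same antibody from cells infected with a lentivirus carrying a short hairpin RNA against Tet1 (replicates 3 and 4). IgG control comprised immunoprecipitations with non-specific IgG from wild-type cells (replicate 1) and mock cells (replicate 2). Infected cells were sorted for GFP 8 days after infection. Wild-type and mock cells were grouped as control cells, and each Tet1 control library was also compared with the IgG library of the same culture type, here called the wild-type pair and the mock pair.

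The libraries differed widely in depth. Tet1 control 1, Tet1 KD 3 and IgG control 1 held 35616255, 36044186 and 29810104 reads and are called the deep set. Tet1 control 2, Tet1 KD 4 and IgG control 2 held 9436346, 3041334 and 8129280 reads and are called the shallow set. After reads at one position and strand were counted once, 31589957, 31881256 and 20147559 positions remained in the deep set and 8428178, 2276009 and 4336907 in the shallow set. Repeated positions made up 10.6% of reads in Tet1 control 1, 10.7% in Tet1 control 2 and 10.5% in Tet1 KD 3, against 25.2% in Tet1 KD 4, 31.5% in IgG control 1 and 46.7% in IgG control 2. The correlation between the strands on chromosome 19 at its best shift exceeded that at a shift of 1000 bp by 0.00756 in Tet1 control 1, 0.00219 in Tet1 KD 3 and 0.00318 in IgG control 1. The same difference was 0.00442 in Tet1 control 2, 0.00032 in Tet1 KD 4 and 0.0020 in IgG control 2.

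The first comparison asked where the Tet1 antibody recovered more chromatin than IgG in control cells. In the wild-type pair, 30367 of 1543116 tested 1 kb bins held at least 2-fold more Tet1 reads than IgG reads by an exact binomial test. In the mock pair 10217 bins did, and 8413 of these (82.3%) were also called in the wild-type pair, where independent lists would share 201.1. That number spreads calls evenly over all tested bins, of which 83.5% held under 60 reads over the 6 libraries. It therefore makes no allowance for read number. With at least 4-fold over IgG, 6421 bins were called in the wild-type pair and 10102 in the mock pair, and 1444 were shared (14.3% of the mock and 22.5% of the wild-type bins). With the wild-type pair thinned to the depth of the mock pair it called 410 bins, of which 340 (82.9%) were among the 10217 of the mock pair (3.33% of these), so at like depth more bins were called in the mock pair. Across bins with at least 60 reads, the Tet1 over IgG ratios of the pairs had a Spearman correlation of 0.34, and among the 8413 shared bins it was 0.06; bins are not independent replicates. Each pair test compares the libraries of that pair. Of simulated bins raised 4-fold, 72.9% were called in the wild-type pair and 3.34% in the mock pair.

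In the test over all 6 libraries, 2601 bins were higher and 73 lower in Tet1 control than in IgG (moderated quasi-Poisson test, Benjamini-Hochberg adjusted, threshold 0.05). The spread in this test came mostly from the mean of bins of similar read number. The median log2 fold of the 2601 bins was 2.34. Simulated reads varied by counting error around a rate per bin that differed between the depth sets. Of 1368024 simulated bins with no change, 3.59% had an unadjusted p under 0.05 by this test. At the largest unadjusted p called in the data, 11 of them were higher and 6 lower. These counts depended strongly on the setting: with the depth set as a block 71416 bins were higher and 29218 lower, other settings gave between 0 and 126091 higher bins, and with all reads as deposited 0 were higher (quasi-Poisson test; 91148 at an unadjusted p under 0.05, and 48343 by limma voom on distinct positions). Higher bins numbered 0 without IgG control 1 (67448 at an unadjusted p under 0.05) or without IgG control 2 (101453), 17114 without Tet1 control 2, 8531 without Tet1 control 1, 812 without Tet1 KD 3 and 931 without Tet1 KD 4, and lower bins 4, 0, 1436, 106, 35 and 51 in the same order.

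The bins with the largest fitted difference held almost no IgG reads. On chromosome 11, the bin from 96586001 to 96587000 (mm8, as are all positions given here) held 37 Tet1 control reads and 0 IgG reads over both libraries of each group, a rate at least 7.55-fold higher when set against 3 IgG reads over the group. On chromosome X, the bin from 44536001 to 44537000 held 58 Tet1 control reads and 1 IgG read, a ratio of 35.5 (95% exact interval 6.12 to 1425). The ratios were 28.8 (4.92 to 1160) on chromosome 9 at 61137001 to 61138000, 25.7 (4.37 to 1039) on chromosome 11 at 68806001 to 68807000, and 19.9 (5.29 to 168) on chromosome 9 at 108802001 to 108803000. In these 5 bins Tet1 KD 3 held 13 to 29 reads (0.408 to 0.910 CPM, reads scaled to the library total), Tet1 control 1 held 28 to 48 (0.886 to 1.52 CPM) and IgG control 1 held 0 to 2 (0 to 0.0993 CPM), while Tet1 KD 4 held 0 to 2 reads. In the bin from 68806001, Tet1 KD 3 held 29 reads and Tet1 control 1 held 28. The bins had been chosen by their fold over the same IgG libraries. Among bins lower in Tet1 control, that on chromosome 2 from 60203001 to 60204000 held 11 Tet1 control and 44 IgG reads, a ratio of 0.153 (0.0712 to 0.301), and that on chromosome X from 3047001 to 3048000 held 7 and 35 reads, a ratio of 0.122 (0.0459 to 0.280). The remaining bins named by the rule lay on chromosome 4 at 146177001 to 146178000 (ratio 0.162) and 146604001 to 146605000 (ratio 0.201) and on chromosome X at 122235001 to 122236000 (ratio 0.207). In the 5 lower bins Tet1 KD 3 lay at 0.251 to 1.69 CPM, Tet1 control 1 at 0.190 to 0.728 and IgG control 1 at 1.64 to 3.62. None of these 10 bins passed the threshold without IgG control 1, without IgG control 2 or with all reads as deposited, and the 5 lower bins and 2 of the 5 higher bins did not pass it without Tet1 control 1. The higher bin on chromosome 11 from 68806001 and the lower bin on chromosome X from 122235001 also failed it narrowly without Tet1 KD 3 (quasi-Poisson adjusted p = 0.0504 for both) and without Tet1 KD 4 (adjusted p = 0.0502 and 0.0552); over all settings their adjusted p ran from 3.48e-07 to 0.583 and from 3.75e-07 to 0.949. Fitted log2 folds of the lower bins were -2.82 to -1.66 with all reads as deposited, -3.05 to -2.43 without IgG control 2, -3.23 to -2.10 without Tet1 control 1 and -1.64 to 0.30 without IgG control 1, and the higher bins stayed higher in each.

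Joined where they touched, the 8413 bins enriched in both pairs formed 6691 regions that covered 8.41 Mb, or 0.32% of the genome bins. Of the regions, 5304 (79.3%) were 1 kb wide, 1333 (19.9%) were 2 or 3 kb wide and 54 (0.81%) were 4 kb or wider. The widest region, on chromosome 14 from 68809001 to 68816000, spanned 7 kb. It held 5.49 and 8.05 CPM per kb (distinct positions scaled to the library total) in Tet1 control 1 and 2, against 1.70 and 0.753 in Tet1 KD 3 and 4 and 1.26 and 0.626 in IgG control 1 and 2. Regions of 6 kb lay on chromosome 2 from 119013001 to 119019000 (4.51 and 5.58 in Tet1 control, 1.40 and 0.805 in Tet1 KD, 1.17 and 0.346 in IgG) and on chromosome 11 from 23976001 to 23982000 (4.34 and 7.08 in Tet1 control, 1.04 and 0.805 in Tet1 KD, 1.09 and 0.461 in IgG). Regions were chosen with the control and IgG libraries in which these levels are given.

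Chromosomes differed in how densely they held enriched regions. Chromosome 11 had 5.25 regions per Mb with reads, chromosome 19 had 4.49 and chromosome 17 had 3.94, while chromosome 14 had 1.34 and chromosome 3 had 1.75. Chromosome X had 0.25 regions per Mb, and none was called on chromosome Y. Fewer bins reached the minimum of 30 reads on chromosome X (17617 of 160208 bins with reads) than on chromosome 11 (89754 of 118706). As a share of tested bins, 0.255% were enriched on chromosome X, 0.358% on chromosome 14 and 0.887% on chromosome 11. IgG control 1 held 5.07 reads per kb with reads on chromosome X, 7.35 on chromosome 14 and 9.02 on chromosome 11. Fewer reads leave less to call with, and neither the densities nor the shares are adjusted for this.

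**Figure D1:**
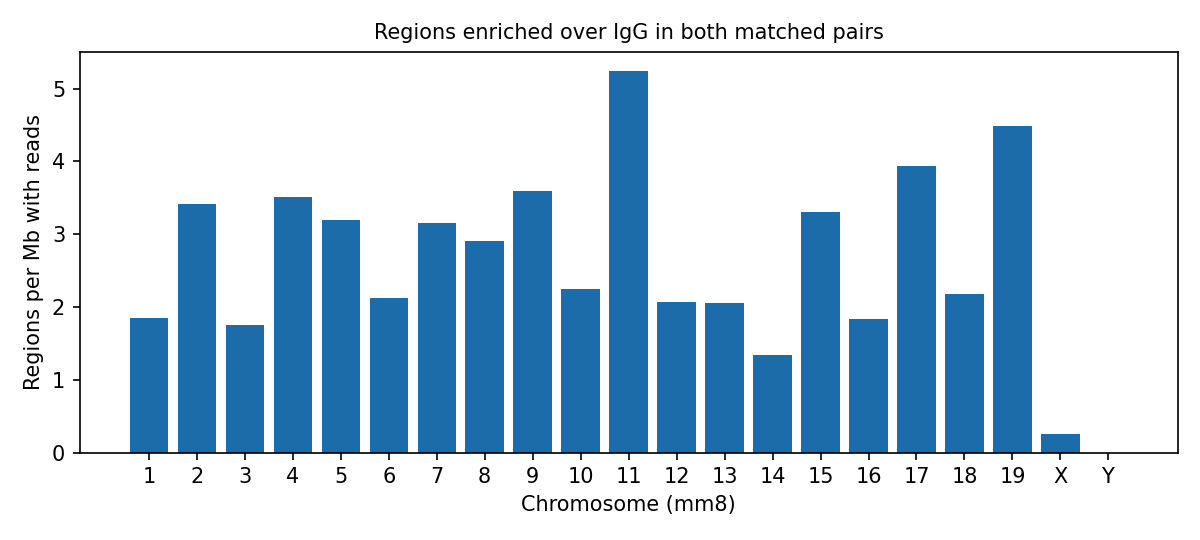
Number of regions enriched over IgG in both matched pairs per Mb of 1 kb bins with reads, by chromosome. Chromosome 11 had the highest density (5.25 regions per Mb) and chromosome X the lowest above 0 (0.25).

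The second comparison asked how the antibody's signal changed on Tet1 knockdown. In Tet1 KD, 22609 bins were lower and 209 higher than in Tet1 control (moderated quasi-Poisson test, adjusted, threshold 0.05). Of 1368024 simulated bins with no change, 101 were lower and 129 higher at the largest unadjusted p called in the data. Of the 2601 bins higher over IgG, 2297 (88.3%) were among those lower in Tet1 KD, and the median log2 change of the 2601 bins on knockdown was -1.99. The median log2 of Tet1 KD over IgG in these bins, which had been chosen with the same IgG libraries, was 0.35. Independent lists would share 38.1 bins, a value that spreads calls evenly over all tested bins. Of the 2601 bins 0.46% held under 60 reads, against 83.5% of tested bins, so it makes no allowance for read number. Among simulated bins with no change, tested against the same control libraries, 0 were called both ways. Part of the excess over these values may come from read number and from the shared control libraries, which this overlap does not split. In bins chosen in one pair and read in the other set, Tet1 KD was at 0.166 times Tet1 control in the shallow set (30367 bins). In the deep set it was at 0.296 times (10217 bins), so a fall was also seen without shared control libraries.

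In the 5 bins named by the rule, log2 folds on knockdown ranged from -3.79 to -3.44. On chromosome 10, the bin from 60542001 to 60543000 held 404 and 167 reads in Tet1 control 1 and 2, 41 and 3 in Tet1 KD 3 and 4, and 36 and 3 in IgG control 1 and 2 (log2 fold -3.44 ± 0.48 SE, quasi-Poisson adjusted p = 0.000377). Also on chromosome 10, the bin from 127024001 to 127025000 held 335 and 175 reads in Tet1 control, 32 and 5 in Tet1 KD and 34 and 1 in IgG (log2 fold -3.52 ± 0.60 SE, quasi-Poisson adjusted p = 0.0013). On chromosome 12 from 81355001 to 81356000 the counts were 243 and 110 in Tet1 control, 26 and 0 in Tet1 KD and 30 and 2 in IgG (log2 fold -3.48 ± 0.62 SE). The bin on chromosome X from 137927001 to 137928000 had the largest fitted fall, at a log2 fold of -3.79 ± 0.81 SE, with 102 and 60 reads in Tet1 control and 8 and 1 in Tet1 KD. On chromosome 5 from 148153001 to 148154000 the log2 fold was -3.54 ± 0.84 SE. These falls did not pass the threshold with all reads as deposited, where the log2 folds were -4.01 to -3.60, or without Tet1 KD 3, where Tet1 KD 4 alone held 0 to 5 reads per bin and the bin with 5 reads, on chromosome 10 from 127024001, had a log2 fold of -2.52.

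**Figure D2:**
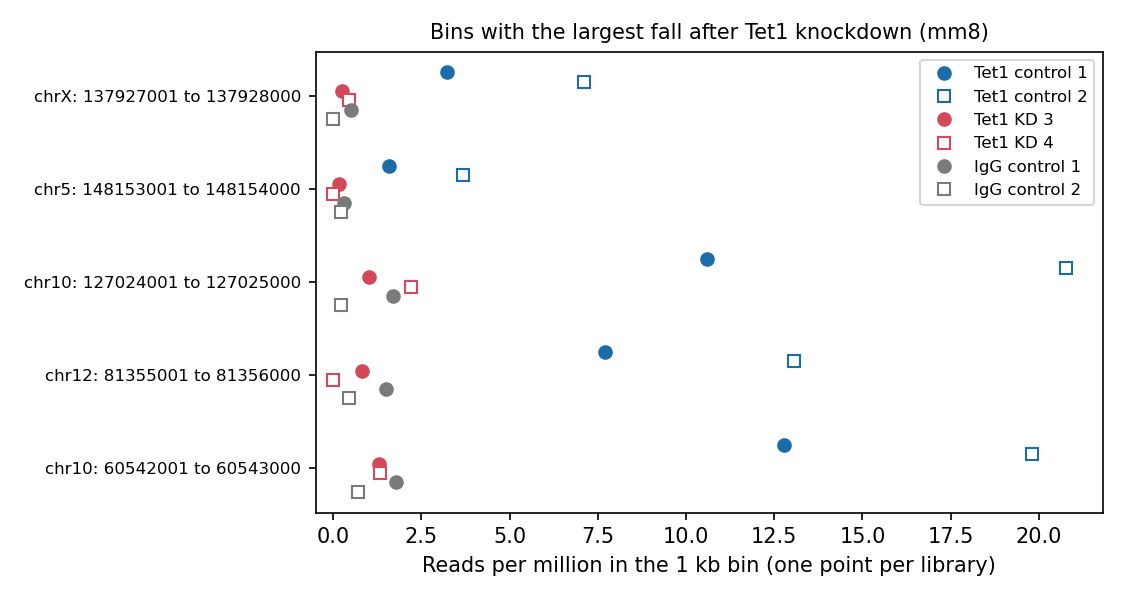
Distinct positions scaled to the library total (CPM) in each library (1 point per library, filled for the deep set and open for the shallow set) for the 5 bins with the largest fall after Tet1 knockdown. At chromosome 10 from 60542001 to 60543000, Tet1 control lay at 12.8 and 19.8, Tet1 KD at 1.29 and 1.32 and IgG at 1.79 and 0.692.

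Higher in Tet1 KD by the rule for named bins were only 3 bins, on chromosome 8 from 131904001 to 131905000 (log2 fold 1.83 ± 0.53 SE), chromosome 6 from 127959001 to 127960000 (1.75 ± 0.49 SE) and chromosome 7 from 38206001 to 38207000 (1.69 ± 0.48 SE). None of these passed the threshold with TMM scaling (log2 folds 1.46 to 1.59), with all reads as deposited (1.75 to 1.99), without either IgG library (1.69 to 1.84), without Tet1 KD 3 (0.61 to 1.81), without Tet1 KD 4 (1.70 to 1.90) or without Tet1 control 1 (1.51 to 2.99), and 1 of the 3 passed it without Tet1 control 2. All 3 passed it by limma voom, with at least 60 reads and with the depth set as a block. Over all bins, 71801 were lower and 15612 higher with the depth set as a block. With all reads as deposited, 0 were lower or higher by the quasi-Poisson test (67699 lower and 29090 higher at an unadjusted p under 0.05). Limma voom, fitted only to distinct positions of all 6 libraries, called 47186 lower and 9542 higher. Without Tet1 KD 3, which left 1 Tet1 KD library, the median log2 of all bins was -0.238, against 0.112 in the main fit. Lower bins numbered 10223 without Tet1 KD 4, and higher bins 97 without Tet1 KD 4, 105 without IgG control 1, 136 without Tet1 control 1 and 558 without Tet1 control 2.

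The third comparison asked what was left of the antibody's signal after knockdown. Bins chosen in one pair were read in the libraries of the other depth set, so that the libraries choosing a bin did not also measure it. The 30367 bins of the wild-type pair held 10.8% of the reads of Tet1 control 2 (95% Wilson interval 10.8 to 10.8), 1.79% of Tet1 KD 4 (1.77 to 1.80) and 2.12% of IgG control 2 (2.10 to 2.13). These bins were 1.15% of the genome bins. The 10217 bins of the mock pair, 0.388% of the genome bins, held 3.95% of the reads of Tet1 control 1, 1.17% of Tet1 KD 3 and 1.38% of IgG control 1. Such intervals cover counting error only.

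**Figure D3:**
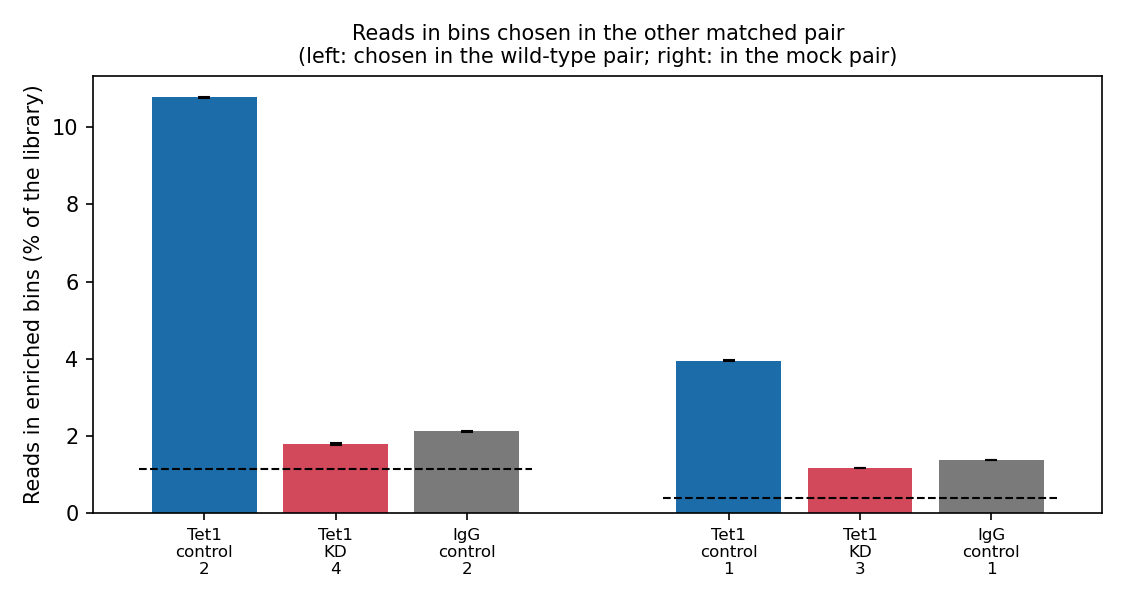
Percent of each library's reads in enriched bins chosen in the other matched pair, with 95% Wilson intervals; dashed lines give the bins' share of the genome bins. Tet1 control 2 reached 10.8% and Tet1 control 1 reached 3.95%, above the Tet1 KD and IgG libraries of the same set.

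Relative to IgG, Tet1 control was 5.09-fold higher in the shallow set and 2.86-fold higher in the deep set over these bins. Tet1 KD was at 0.845 times the IgG level in the shallow set and 0.847 times in the deep set. In the shallow set Tet1 KD 4 had 25 bp reads and IgG control 2 had 36 bp reads, so read length also differed there. In the 6691 regions enriched in both pairs, which had been chosen with the IgG libraries that measure them, Tet1 KD was at 1.11 to 1.22 times the IgG level in the shallow set and at 0.874 to 0.977 times in the deep set, by width of the region. After subtraction of the IgG level, the Tet1 KD signal was -3.79% of the Tet1 control signal in the shallow set (95% interval -4.11 to -3.49, from resampled 1 Mb blocks) and -8.19% in the deep set (-8.63 to -7.72). With each library's own level 4 to 5 kb away as the background, the shares were 5.28% and 19.6%. Within 500 bp of the centres of enriched bins, reads stood at 4.52 times the library's own flanks in Tet1 control 1, 2.08 times in Tet1 KD 3 and 2.65 times in IgG control 1. In the shallow set the values were 3.80 in Tet1 control 2, 1.30 in Tet1 KD 4 and 1.64 in IgG control 2.

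**Figure D4:**
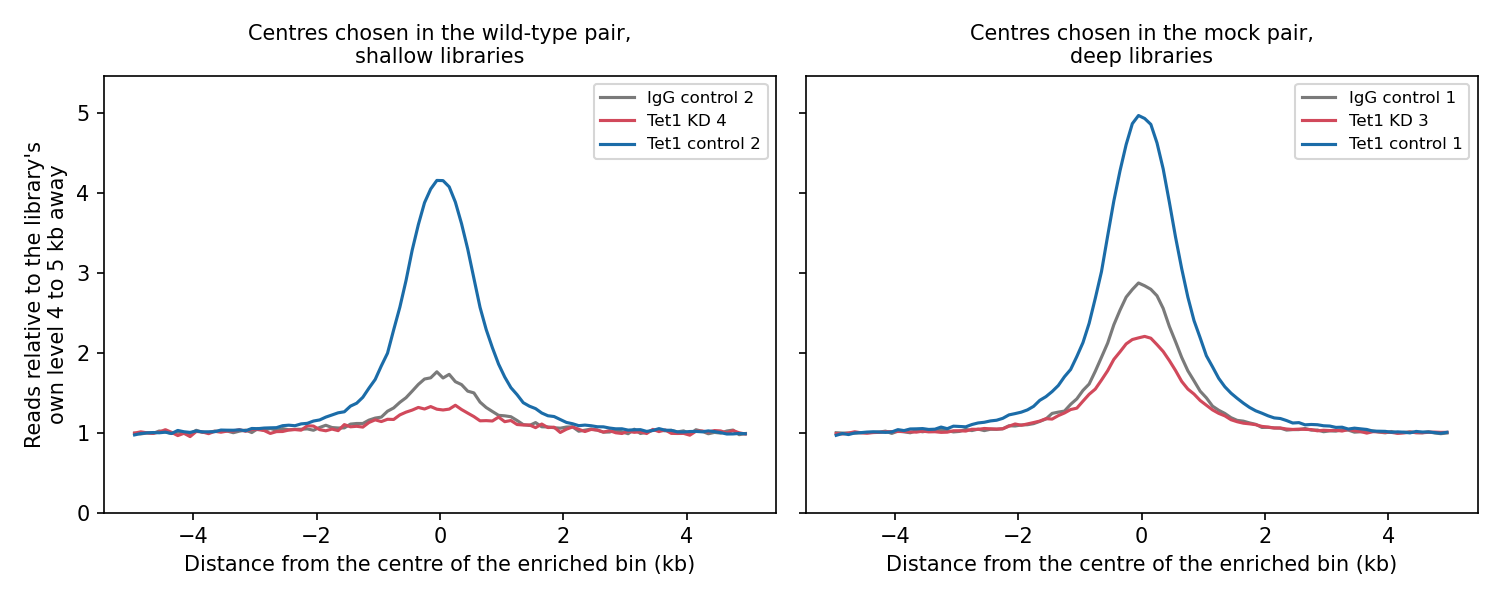
Reads around the centres of enriched bins, in steps of 100 bp, relative to each library's own level 4 to 5 kb away (1 line per library). Left, 20832 centres chosen in the wild-type pair and read in the shallow set; right, 8153 centres chosen in the mock pair and read in the deep set. Within 500 bp of the centre Tet1 control averaged 3.80 and 4.52, IgG 1.64 and 2.65, and Tet1 KD 1.30 and 2.08.

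No bin passed the threshold between Tet1 KD and IgG in the moderated quasi-Poisson test over all 6 libraries. The simulation held no change between these groups, so how many true differences the test would call was not measured. The absence of calls therefore does not show equal levels. At an unadjusted p under 0.05, 37961 bins were higher and 21283 lower in Tet1 KD. By limma voom, 260 bins were higher and 501 lower, and with the depth set as a block 90 were higher and 121 lower. In exact binomial tests against the IgG library of the same set, 2 bins were at least 2-fold higher in Tet1 KD 3 and 0 in Tet1 KD 4, the shallowest library with 2276009 positions. Of 8413 bins enriched in both pairs, 0 were called in Tet1 KD in either set. The IgG libraries came from cells without Tet1 knockdown.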

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

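The deep set also lists reads outside chromosomes 1 to 19, X and Y, which entered no comparison; how these were compared was chosen after the data had been seen. Of 9 contigs with at least 1000 distinct positions in Tet1 control 1 and IgG control 1 together, 1 exceeded IgG by more than 1.5-fold. On the unplaced contig of chromosome 7, Tet1 control 1 had 2870 distinct positions and IgG control 1 had 1063, a ratio of 1.72 after scaling (95% exact interval 1.60 to 1.85). Tet1 KD 3 had 1751 positions there, 1.04 times the IgG level (0.964 to 1.12). With all reads as deposited the ratios were 1.71 in Tet1 control 1 and 1.06 in Tet1 KD 3. On the mitochondrial genome the 78024 reads of IgG control 1 fell on 16163 distinct positions, so positions understate its reads there; by all reads the ratios to IgG were 0.203 in Tet1 control 1 and 0.222 in Tet1 KD 3, and by distinct positions 0.403 and 0.397. On the unplaced contig of chromosome 15 the ratios of positions were 0.577 (0.522 to 0.638) and 0.830, and those of all reads 0.550 and 0.816. On that of chromosome Y the ratio of Tet1 control 1 was 0.582 (0.579 to 0.585) by positions and 0.695 by all reads, and that of Tet1 KD 3 was 0.810 and 0.990. The shallow set lists no such reads, so these values have no replicate, and no explanation was tested.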

How the results depend on the processing

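The numbers of called bins moved by far more than 1.5 times between settings, while the direction of the main differences held wherever bins were called in number. Limma voom, the depth set as a block and this block with TMM factors were chosen after the data had been seen. Counts are given as higher and lower for Tet1 control over IgG, then for Tet1 KD over Tet1 control, then for Tet1 KD over IgG where these moved. The main counts were 2601 and 73, 209 and 22609, and 0 and 0. At least 60 reads gave 46994 and 628, then 367 and 60849. TMM factors gave 38685 and 654, then 56870 lower. Limma voom gave 48343 and 32234, 9542 and 47186, and 260 and 501. The depth set as a block gave 71416 and 29218, 15612 and 71801, and 90 and 121; with TMM factors it gave 126091 and 16443, 7020 and 117101, and 91 and 119. All reads as deposited gave 0 and 3, 0 and 0, and 3 lower. Bins of 2 kb gave 4468 and 167, then 137 higher. TMM factors, voom and both blocks each called all 2601 of the main higher bins. They called many more bins from the same reads, so this is no independent support. In voom and both blocks a bin's own spread between libraries had no weight. All reads as deposited called 0 of the 2601 bins. At least 60 reads tests fewer bins and a block removes the difference between sets from the spread; for the others the cause was not tested. Leaving out 1 library gave 0 to 17114 and 0 to 1436, then 0 to 558 and 0 to 32748, then 0 to 5 lower; a lone library is then assumed to vary like the other groups.

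With the replicate block, on the Tet1 control and IgG libraries, 58569 bins were higher and 24481 lower. A bin's own spread between libraries had no weight in this fit either, with 1 residual degree of freedom and a median dispersion of 1.07. Deviations of Tet1 control 1 and IgG control 1 from their group means correlated at 0.40 across bins, but the number also follows the depth set (0.29 for Tet1 control 1 and Tet1 KD 3), so the libraries are not known to share more than a number and a culture type.

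With own flanks as background, the share of signal left in Tet1 KD turned from negative to 5.28% for bins of the wild-type pair and 19.6% for those of the mock pair; the IgG libraries were themselves raised at these bins. With at least 4-fold over IgG the share was -0.33% for bins of the wild-type pair. Bins called in both pairs fell from 8413 to 1444 with at least 4-fold over IgG and to 340 with the deeper pair thinned to the shallower, which has fewer reads to call with; as a share of the mock pair's bins they fell from 82.3% to 14.3% and 3.33%. Of 226 values of the 18 named bins under other settings, 152 stayed past the threshold, 73 did not, and 1 reversed: the bin on chromosome X from 122235001 had a log2 fold of 0.30 without IgG control 1 (adjusted p = 0.949, quasi-Poisson test), and its values without 1 library ran from -2.84 to 0.30. On the unplaced contig of chromosome 5, Tet1 KD 3 over IgG control 1 turned from 0.852 by distinct positions to 1.05 by all reads as deposited, a comparison chosen after the data had been seen; the cause was not tested. Promoter, gene list and CpG class alternatives were not run, since the gene annotation at hand belongs to another assembly and coordinates were not converted.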

Other observations

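Tests on the lower bins and on the chromosomes were chosen after their results had been seen in part; tests on the signal left after knockdown were fixed before their values were seen. The Tet1 signal was graded among enriched bins. With bins ranked by Tet1 control reads in the pair that chose them and parted into 4 groups of equal size, from the weakest to the strongest group Tet1 control over IgG in the other set rose from 3.26-fold to 6.48-fold in the shallow set and from 2.52-fold to 3.27-fold in the deep set. Tet1 KD over IgG was 0.976 and 0.767 in these groups in the shallow set and 0.908 and 0.807 in the deep set. Among the widest regions were also 5 kb on chromosome 14 from 24290001 to 24295000, with 7.16 and 9.87 CPM per kb in Tet1 control, 1.46 and 1.49 in Tet1 KD and 1.63 and 1.20 in IgG, and 5 kb on chromosome 7 from 82741001 to 82746000, with 5.78 and 9.06, 1.39 and 0.791, and 1.49 and 0.830.

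A few places held dense reads in all libraries of the deep set, IgG included. On chromosome 17 from 39451001 to 39457000, Tet1 control 1 filled 10905 of 12000 possible positions, IgG control 1 9574 and Tet1 KD 3 9810. In the shallow set Tet1 control 2 filled 6554, IgG control 2 5741 and Tet1 KD 4 1469. On chromosome 9 from 3000001 to 3038000, the deep set values were 44204, 44762 and 43782 of 76000 positions. The shallow set values were only 985, 998 and 387 in the same order of groups. Why the sets differed there was not tested.

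After knockdown, the Tet1 antibody's signal over enriched bins chosen in the other set lay at 0.845 and 0.847 times the IgG level, while the median log2 of Tet1 KD over IgG was 0.35 in the 2601 bins chosen with the same IgG libraries, a choice that by itself raises this value. Too few reads in the Tet1 KD libraries are argued against by the deep set, where Tet1 KD 3 was about as deep as Tet1 control 1 and its excess over IgG was -8.19% of that of Tet1 control 1 (95% interval -8.63 to -7.72). Choosing bins in the libraries that measure them is argued against too, since the larger of the shares from cross-chosen bins was -3.79%; against each library's own flanks the shares were 5.28% and 19.6%. A lower yield of immunoprecipitation in the Tet1 KD libraries could give the same loss: in 0 of 8 groups of bins by strength was the share above 0, so weak and strong bins could not be compared. A lower yield and a loss of Tet1 from chromatin therefore cannot be told apart, and the knockdown itself was not measured in these files. In the deep set Tet1 KD 3 came from infected, sorted cells, while Tet1 control 1 and IgG control 1 came from wild-type cells. Infection and sorting are therefore mixed with knockdown there, and the pooled group folds rest mostly on that set. Only the shallow set, with mock-infected controls, compares infected cells with infected cells.

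Away from enriched bins (over 10 kb from any bin called in either pair, 1228503 bins), Tet1 control was compared with IgG by chromosome. Here each library was scaled to its own reads in these bins. Log2 ratios above 0 on some chromosomes and below 0 on others thus follow from the scaling and show no level relative to IgG. The log2 ratio of Tet1 control over IgG by chromosome ran from -0.10 to 0.12 in the deep set and from -0.14 to 0.17 in the shallow set. Across the 19 autosomes it rose with enriched bins per Mb counted in the other pair, with Pearson r = 0.877 and Spearman rho = 0.833 in the deep set and r = 0.887 and rho = 0.872 in the shallow set (permutation p = 1e-05 for both r, the smallest that 100000 permutations can give; adjusted p = 2e-05 over 4 relations), and r was 0.788 and 0.834 without the 2 chromosomes of most extreme density. Enrichment too weak to be called stays open: the r of at least 0.877 is the pattern itself, seen before the test, and adds no support. A bias shared by both antibody libraries of a set stays open. In the shallow set the Tet1 KD slope was -5.38% of the Tet1 control slope. Tet1 KD 4 had 25 bp reads and the other libraries of that set 36 bp, so this slope also holds the difference in read length. In the deep set, with 25 bp reads throughout, the Tet1 KD slope was 27.1% of the Tet1 control slope (95% interval 5.65 to 39.7). Tet1 KD r was 0.539 there (permutation p = 0.0168, adjusted p = 0.0224), but rho was 0.351 (permutation adjusted p = 0.189). Without the 2 chromosomes farthest in density, on which it rests, r was 0.260. Sequence composition was not tested.

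Of the 73 bins lower in Tet1 control than in IgG, 94.5% stayed called lower with TMM factors. These factors moved the median log2 of all bins by 0.234, against a median log2 of -3.07 in the 73 bins. That outcome was thus nearly fixed in advance. It covers only the choice between these scalings, and other scalings were not tested. Sequence present in many copies was not decided: IgG control 1 held a median of 21 reads in these bins against 9 in all tested bins, 2.33 times as many, but the bins had been chosen for many IgG reads, which alone raises this value. A difference between antibody and IgG libraries that does not need Tet1 also stays open. A first version of this test used the 73 bins, where the median log2 of Tet1 KD over IgG was -1.20, and was replaced after this value was seen, because the bins had been chosen with the same IgG libraries, which alone pushes it below 0. In bins chosen as lower in one pair and read in the other set, Tet1 KD over IgG was -0.35 (95% interval -0.47 to -0.27, 485 bins) and -0.88 (-1.06 to -0.75, 32 bins), and Tet1 control over IgG was -1.09 and -0.92. These intervals came from resampled single bins, treat neighbouring bins as independent and may be too narrow.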
